A study of Homo sapiens with 8 samples.

How the data were processed

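RNA of the cytoplasm of U2OS cells was extracted, fragmented to about 100 nt and, in the m6A libraries, immunoprecipitated with an antibody against m6A, per the labels' protocols. The 8 libraries are 2 input and 2 m6A libraries each for control and DF2 siRNA cells. The labels number the DF2 siRNA libraries 1 and 2 without saying whether these are different siRNAs or replicates of 1 siRNA, and nothing says whether the pairs came from separate cultures. Reads were aligned with HISAT2 to hg38, per the submitters' processing notes. The HISAT2 version, the peak caller, its settings, the annotation, the filters and the use of strand are not given in the sources used here.

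The authors deposited 2 peak lists, and each list belongs to both immunoprecipitates of a condition, per the labels, so peaks were not given per library. A peak is 1 or more blocks within exons, named by its Ensembl gene and a bin number, and 87.2% of control peaks and 90.9% of DF2 siRNA peaks were a multiple of 200 nt long. The deposited fold enrichment is a ratio per peak, per the file headers, and what it is relative to is not given in the sources used here. The deposited −log10 value is that of a p-value in the control list and of an FDR in the DF2 siRNA list, per the file headers, yet its minimum was 1.30 in both. A stricter limit on it is therefore not the same limit in both lists. The deposited score is a whole number of at least 3 without a stated meaning. In peaks of 1 bin, each of the 952 distinct pairs of fold enrichment and −log10 value in the control list, and each of the 837 in the DF2 siRNA list, went with 1 score, as for a value computed from a count. Fold enrichment and score are the authors' values and serve to describe, rank and filter peaks within a list. Wide peaks add up more sequence, so such values also depend on how bins were joined, and all of them depend on library depth, which is unknown. The feature label of a peak (5′ UTR, coding, stop codon, 3′ UTR, non-coding RNA or several of these) is the authors' own. It was missing for 378 control peaks and 246 DF2 siRNA peaks, which stayed in the denominators.

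Coordinates are those of the lists, counted from 1. Overlap was computed on the exonic blocks with at least 1 shared base on the same strand. Chance overlap came from 100 seeded shuffles of each peak within its chromosome. Genes were counted by the Ensembl gene of the peak. A peak with several feature labels was given 1, in the order stop codon, 3′ UTR, coding, 5′ UTR, non-coding RNA. For the gene lists, the 10506 gene names in the peak lists were matched to RefSeq genes of GRCh38.p14 by symbol (8509) or by a unique older name (640), if a peak lay within 100000 bp of that gene; 11 lay elsewhere and 1346 had no match. This distance was set after the lists were seen, since a first limit, peaks within 10000 bp of the gene's ends, had left out genes with longer older models. For each gene list, 10000 seeded random lists were drawn with matched deciles of genomic span. The percentile is that of the number of control-only minus DF2 siRNA-only genes. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

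The gene lists, the rule for naming genes, the comparisons and most alternatives were set before the data were examined. Genes were named by this rule: YTHDF2, the 10 genes with the highest fold enrichment per list, the 8 highest with a peak in 1 list only, the 6 with the largest surplus of peaks in each direction, and from each gene list up to 4 members per direction found in 1 list only and the 3 highest found in both. MUC16 led the surplus in control. PLK1 and GABARAPL1 fall outside the rule and were named to complete groups of 5, after their values were seen. Some genes that the rule selects are not reported here. The alternatives were stricter limits, equal list lengths, merging of near peaks, a reciprocal overlap, overlap without strand, 2 peaks per gene, RefSeq gene names and chromosomes 1 to 22 and X. Added after the data were seen were a score floor, peaks of at most 400 nt, peaks with 1 feature only, and overlap of whole spans. The score floor was 10 in the DF2 siRNA list and 23.5 in the control list, which is 10 divided by 0.425, the median ratio of the scores at identical intervals. The sequence motif of m6A, positions measured from the stop codon and shuffles within transcripts were planned and were not analysed here, since no genome sequence or transcript models were used. For the same reason, shuffles ran over chromosomes, random lists were matched on genomic span in place of exonic length, and the authors' labels took the place of positions computed from transcripts. Values per library were not analysed here.

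The procedures were tested on simulated data. A copy of the control list with 30, 60 or 90% of its 15730 peaks kept in place gave an overlap of 30, 60 and 90%, which checks the counting only. Among 200 random gene lists of 35 members drawn from 8000 simulated genes, 4% fell outside the central 95% of matched lists, and 92% of lists with 10 planted members lay above percentile 97.5. These random lists came from the same genes as the matched lists, and no difference between control-only and DF2 siRNA-only genes was simulated. The simulation therefore does not cover gene lists richer in genes with peaks than their matched lists.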

Results

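The methylated adenosine m6A was mapped in U2OS cells, a human osteosarcoma line, with and without siRNA against YTHDF2 (DF2). YTHDF2 is a cytoplasmic protein that binds m6A in mRNA and directs the bound mRNA to decay. The comparison asked where m6A lay in cytoplasmic RNA of cells with and without this siRNA. Cytoplasmic RNA was broken into short fragments, and fragments with m6A were enriched with an antibody. The 8 libraries formed 4 groups of 2: input RNA and m6A immunoprecipitate of control cells, and the same pair for DF2 siRNA cells. The values used here are 2 lists of peaks, 1 per condition, and the labels tie each list to both immunoprecipitates of its condition. Library depths are unknown. With 1 list per condition, differences between conditions have no replicate check, so they are described without p-values. Intervals of shares are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only. Intervals of differences in share are 95% normal approximations. They treat the 2 lists as independent, although most peaks overlap between them.

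YTHDF2, the targeted gene, carried 1 peak in each list. In control cells the peak ran from 28740371 to 28769316 on chromosome 1 (hg38), with 2000 nt of exonic sequence labelled 5′ UTR, coding, stop codon and 3′ UTR, a deposited fold enrichment of 124 and a deposited score of 4226. In DF2 siRNA cells it ran from 28742575 to 28743974, with 1400 nt labelled coding and stop codon, a fold enrichment of 52.3 and a score of 185. Within its own list, the control score of YTHDF2 stood at percentile 99.1, with 147 peaks above it, and the DF2 siRNA score at percentile 71.5, with 3757 peaks above it. What the score counts is not given in the sources used here, so these values do not measure the level of YTHDF2 mRNA, and the depth of the knockdown was not analysed here.

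Control cells had 15730 m6A peaks in 9971 Ensembl genes and DF2 siRNA cells had 13219 peaks in 8556 genes. Peaks had a median of 600 nt of exonic sequence in both lists (interquartile range 400 to 1000 nt in both). They covered 12.4 Mb in the control list and 9.87 Mb in the DF2 siRNA list. The median fold enrichment was 20.8 in control (interquartile range 11.3 to 43.1) and 17.7 in DF2 siRNA (10.7 to 34.2). The median score was 143 in control and 74 in DF2 siRNA. Genes with 2 or more peaks made up 38.9% of the genes of the control list and 37.4% of those of the DF2 siRNA list. The mucin gene MUC16 held the most peaks in both, 18 in control and 11 in DF2 siRNA. The number of peaks in a list moves with the reads behind it, and that number is unknown for both lists.

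Most m6A peaks of DF2 siRNA cells lay on peaks of control cells. Of the 13219 DF2 siRNA peaks, 87.5% (86.9 to 88.1%) shared at least 1 base with a control peak on the same strand, and 1653 did not. Of the 15730 control peaks, 71.9% (71.2 to 72.6%) were overlapped by a DF2 siRNA peak, and 4423 were not. Random placement of the peaks on their chromosomes gave a mean overlap of 0.738% for DF2 siRNA peaks and 0.635% for control peaks over 100 shuffles. Because transcribed exons fill a small part of a chromosome, this chance level is lower than a placement within exons would give. Altogether 4643 peaks had identical intervals in both lists, 29.5% of the control peaks and 35.1% of the DF2 siRNA peaks.

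The peaks found in control only were mainly those with low scores. In the lowest quintile of the control list by score, 26.5% of peaks (24.9 to 28.1%) were overlapped by a DF2 siRNA peak. In the highest quintile the share was 97.1% (96.4 to 97.6%). Among DF2 siRNA peaks, overlap with the control list went from 75.2% (73.5 to 76.8%) in the lowest quintile to 98.1% (97.5 to 98.6%) in the highest. When only the 13219 control peaks with the highest fold enrichment were kept, so that both lists were equally long, 81.4% of control peaks and 83.7% of DF2 siRNA peaks overlapped.

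**Figure D1:**
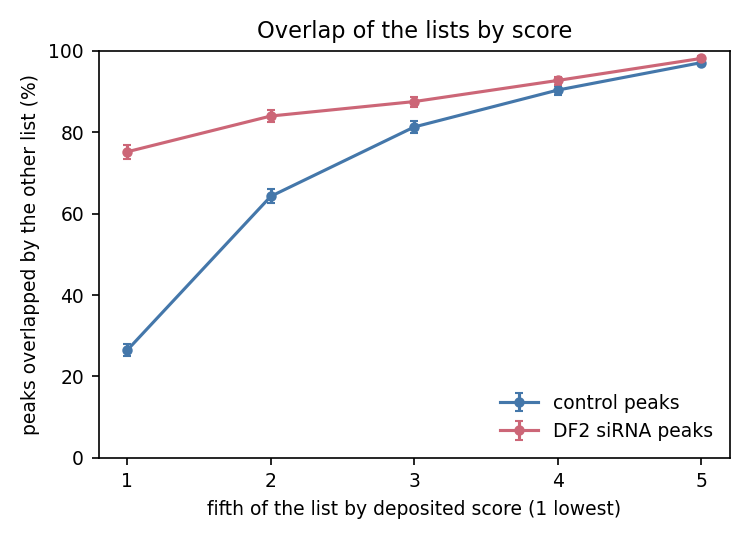
Share of the peaks of each list (%, y axis) overlapped by a peak of the other list, by quintile of the deposited score within the list (x axis, 1 lowest). Bars are 95% exact binomial intervals. The share of control peaks overlapped goes from 26.5% in the lowest quintile to 97.1% in the highest, that of DF2 siRNA peaks from 75.2% to 98.1%.

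A peak in both conditions was found in 7950 genes, in control only in 2021 genes, and in DF2 siRNA only in 606 genes. Of the genes in the control list, 79.7% were also in the DF2 siRNA list, and of the genes in the DF2 siRNA list, 92.9% were also in the control list. Genes in 1 list only had weak peaks. The best peak of a control-only gene had a median fold enrichment of 10.6, against 37.3 for the control peaks of genes in both lists. For DF2 siRNA-only genes the median was 9.96, against 25.1. With lists of equal length, the number of control-only genes was 1205, and that of DF2 siRNA-only genes was 874. Only control peaks were dropped for this, so the first number could only fall and the second could only rise.

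The strongest genes found in control only were KIAA0825 (chromosome 5, 94520068 to 94524079, fold enrichment 112, score 292), the zinc finger gene ZNF107 (103, score 283), CCDC186 (98.5, score 416) and GNRHR2 (89.6, score 122, labelled non-coding). Among the next were KATNBL1 with a fold enrichment of 82.4, MCF2L2 with 71.1 and COX6B2 with 68.9. The strongest genes found in DF2 siRNA only had lower values within their list. They were NUS1 with a fold enrichment of 35.2, the p53 relative TP73 (chromosome 1, 3732839 to 3734038, around the stop codon) with 33.6, PPP1R14B with 31.8 and the transcriptional repressor HIC1 with 30.5 and 3 peaks. PARD6G followed with 28.7, the Polycomb component RING1 with 28.6, GCNT3 with 25.8 and TENM4 with 25.6.

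The largest differences in number of peaks per gene were those of MUC16, given above, and of the following genes. The cytoskeletal linker gene DST had 14 peaks in control and 8 in DF2 siRNA. AKAP6, an anchoring protein for protein kinase A, had 6 and 0, RPAP2 had 7 and 2, PECAM1 had 5 and 0, and MTCL1 had 8 and 4. The best peaks of AKAP6 and PECAM1 had scores of 19 and 39, below the control median of 143. In the other direction, the ubiquitin ligase gene RNF213 had 5 peaks in control and 8 in DF2 siRNA, and ALMS1 had 3 and 6. ZDBF2 and ZNF37BP had 2 and 5 each, and DCLRE1A and HELZ2 had 1 and 4 each. In HELZ2 the single control peak covered 3600 nt of coding sequence, and 1 of the 4 DF2 siRNA peaks spanned it. In DCLRE1A, ZDBF2 and ZNF37BP the best control peak was the wider one and contained the best DF2 siRNA peak. Their widths were 3200 and 600 nt, 3000 and 800 nt, and 2200 and 1000 nt. A higher number of peaks in DF2 siRNA can therefore come from how bins were joined.

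The genes with the highest fold enrichment carried peaks in both conditions. In control cells the 10 highest included the GTPase gene ARF6 (chromosome 14, 49893590 to 49894589), HAGHL, N4BP3, LRFN1, DNAJC22, EPPK1, CISH, LMLN and the receptor gene ROR2, with fold enrichments from 239 to 320.3. All 10 also had a peak in DF2 siRNA cells. ARF6 was listed at 320.3 in control and 93.4 in DF2 siRNA over the same interval, and the cytokine signalling inhibitor CISH at 259 and 49.4. In DF2 siRNA cells the leading genes were SMAD6, an inhibitor of BMP signalling, LMTK3, EPPK1, the kinase gene DAPK3, LRFN4, the amino acid transporter gene SLC7A5, IER5L, ZNF865, LRFN1 and FOXA1, with fold enrichments from 223 to 369. All 10 also had a peak in control cells. SMAD6 was listed at 164 in control and 369 in DF2 siRNA over the same interval of chromosome 15 (66702228 to 66704427). The 3′ UTR peak of SLC7A5 had the highest score of both lists, 53084 in control and 29600 in DF2 siRNA. Fold enrichments are the authors' values within a list, and no difference between the lists was tested on them.

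In both conditions many m6A peaks touched a stop codon. A peak can carry several labels. Counting every label, coding sequence was given for 61.7% of control and 66.4% of DF2 siRNA peaks and the 3′ UTR for 55.2% and 55.0%. With 1 label per peak, the stop codon first in the order, 42.7% of control peaks (42.0 to 43.5%) and 43.7% of DF2 siRNA peaks (42.8 to 44.5%) touched a stop codon. The 3′ UTR held 18.5% (17.9 to 19.1%) and 18.0% (17.3 to 18.7%), the 5′ UTR 7.43% (7.03 to 7.85%) and 7.53% (7.09 to 8.0%). Coding sequence held 15.5% of control peaks (14.9 to 16.1%) and 19% of DF2 siRNA peaks (18.3 to 19.6%). Non-coding RNA held 13.5% of control peaks (12.9 to 14%) and 10% of DF2 siRNA peaks (9.49 to 10.5%). The intervals of the coding share and of the non-coding share did not overlap between the lists. In peaks of at most 400 nt, the stop codon shares were 22.6% in control and 24.9% in DF2 siRNA. The stop codon share thus depends on peak width and on the order of the labels, and the shares expected by chance were not computed. With lists of equal length the non-coding shares were 11% and 10%, and the stop codon shares were 48.2% in control and 43.7% in DF2 siRNA. Only control peaks of low fold enrichment were dropped for this. The median fold enrichment of control peaks was 33.1 for stop codon and 14.1 for non-coding RNA peaks, so the dropping itself shifts these shares.

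**Figure D2:**
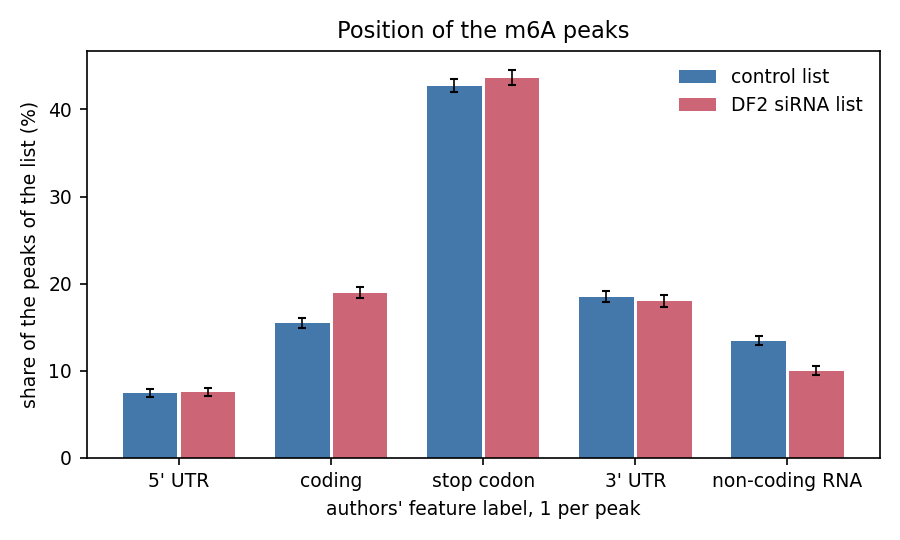
Share of the peaks of each list (%, y axis) by the authors' feature label, with 1 label per peak (x axis). Bars are 95% exact binomial intervals. Stop codon peaks make up 42.7% of the control list and 43.7% of the DF2 siRNA list, non-coding RNA peaks 13.5% and 10%.

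Control peaks in non-coding RNA and untranslated regions were overlapped by a DF2 siRNA peak less often than those at stop codons. Stop codon peaks of the control list were overlapped in 83.7% of cases (82.8 to 84.5%), coding peaks in 77.5% (75.8 to 79.2%), 3′ UTR peaks in 64.0% (62.2 to 65.8%), 5′ UTR peaks in 56.4% (53.5 to 59.2%) and non-coding RNA peaks in 52.7% (50.6 to 54.9%). Their median scores followed the same order, at 338, 179, 95, 37 and 27. Peak width was not matched between the features. Among DF2 siRNA peaks, 5′ UTR peaks were the least often overlapped, at 64.3% (61.2 to 67.2%), and non-coding RNA peaks were overlapped in 88.7% of cases (86.8 to 90.3%).

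The 17 gene lists fixed beforehand had 562 distinct members, of which 328 had a control peak, 309 had a DF2 siRNA peak and 217 had neither. The number of members with a peak in either list stood at percentile 98.4 or above of random lists matched on genomic span, except for oxidative phosphorylation (65.3) and the markers of other cell types (38.2). The random lists also drew genes that these cells may not express. Where 2 fold enrichments are given for a gene below, they are those of its best peak in control and of its best peak in DF2 siRNA, which can lie at different sites, as in NSD1, COL5A1, RNF168 and IFNAR1. Several genes named below in 1 list only had −log10 values near the minimum of 1.30, such as ATG13 (1.31), YTHDC2 (1.37), RPL6 (1.41) and CDKN1A (1.60). Others, such as WRN (7.98) and RPS24 (17.3), lay far above it. A peak near the minimum can be missing from the other list through a small difference. Genes of transcription factors and chromatin regulators carried peaks in both conditions. Of 32 immediate early and growth-related factors, 30 had a peak in both lists and none in 1 list only. Of 30 random control genes matched on score, a median of 28 were also in the DF2 siRNA list. FOSL2, a partner of JUN, was listed at a fold enrichment of 139 in control and 155 in DF2 siRNA, and the immediate early gene IER2 at 129 and 150.05. MYC had its best peak at the stop codon and 3′ UTR (chromosome 8, 127740634 to 127741433) in both lists, at 132 and 58.5. Of 50 chromatin regulators, 45 had a peak in both lists and none in 1 list only, among them KMT5B (151 and 39.7), ARID1B (130.5 and 118) and NSD1 (129 and 65.4). The median for random control genes matched on score was 43 of 45. Of 39 genes of Wnt, Notch, Hippo and TGF-beta signalling, 31 had a peak in both, 2 in control only (AXIN2, SMAD4) and 1 in DF2 siRNA only (DVL3). The receptors FZD7 (184 and 46.5) and NOTCH2 (127 and 58.4) were among those in both. Of 30 osteoblast and matrix genes, 17 had a peak in both lists and none in 1 list only, with TNC at 179 and 127, the growth factor gene BMP2 at 133 and 96.3 and the collagen gene COL5A1 at 98.0 and 41.6. The matched median was 15 of 17. Single-list members appeared in the upper 50% by fold enrichment, with p or FDR 100 times smaller, and with 2 peaks or more per gene. In this order, control-only and DF2 siRNA-only genes numbered 2 and 1, 3 and 0, and 5 and 3 for immediate early factors. They numbered 4 and 3, 5 and 2, and 5 and 3 for chromatin regulators, and 2 and 1, 0 and 1, and 3 and 1 for matrix genes.

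Transcripts of the m6A machinery carried peaks themselves. Of 23 writers, erasers and readers, 18 had a peak in both lists, among them IGF2BP3 (fold enrichment 207 in control and 26.9 in DF2 siRNA) and the writer component RBM15 (139 and 124). The reader YTHDC2 had a peak in control only (8.34) and the methyltransferase gene METTL3 in DF2 siRNA only (13.9). Of 30 genes of deadenylation and mRNA decay, 16 had a peak in both lists, among them the helicase DDX6 (105 and 53), UPF1 of nonsense-mediated decay (88.4 and 133) and TOB1 (88.0 and 64.6), and 2 in control only (CNOT11, RIDA). Of 24 long non-coding RNAs, 12 had a peak in both lists. NORAD was listed at 86.8 with a score of 3962 in control and at 118 with a score of 3160 in DF2 siRNA, MALAT1 at 82.2 with 22404 and 36.9 with 2936, and TUG1 at 79.9 with 1610 and 61.3 with 544. HOTAIR had a peak in control only (21.3, score 204).

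Ribosomal protein genes had a larger surplus in control only than most random lists, and DNA repair, heat shock and oxidative phosphorylation genes had one within the central 95% of random lists. Of 50 cytosolic ribosomal proteins, 7 had a peak in both lists, with RPL37 (54.1 and 41.6), RPL13 (44.2 and 45.9) and RPL3 (24.1 and 11.3) the strongest, 6 in control only and 0 in DF2 siRNA only. RPS24 (35.9), RPL4 (19.6, score 2823), RPL6 (10.3) and RPS14 (9.83) led those in control only. The surplus of 6 control-only genes stood at percentile 99.8 of 10000 random lists matched on genomic span, whose median was 1. Those lists had a median of 7 members with a peak, against 13 with a control peak here. They left less room for a surplus, so the percentile can be too extreme. The ribosomal protein genes numbered 4 in control only and 1 in DF2 siRNA only with equal list lengths, and also with a score floor scaled between the lists, 2 and 1 in the upper 50% by fold enrichment, and also with p or FDR 100 times smaller, and 1 and 0 with 2 peaks or more per gene. Of 13 with a control peak, 7 were also in the DF2 siRNA list, at percentile 1.92 of random control genes matched on score. RPL4 and RPL6 (score 236) lay above the median control score of 143 but below the median fold enrichment of 20.8. RPS24 (score 53) lay the other way. Matching on score thus did not match enrichment, and this percentile cannot tell a loss from weak enrichment. Of 35 DNA damage genes, 18 were in both, with RNF168 (119 and 54.4), the helicase BLM (100.3 and 22.6) and LIG4 (97.9 and 25.5) the strongest, and 5 in control only, among them WRN (30.1), XRCC6 (12.8) and RPA1 (10.4), at percentile 88.3. Of 30 genes of heat shock and the unfolded protein response, 21 were in both, with DDIT4 (72.9 and 97.3), PPP1R15B (69.6 and 55.2) and HSPA1B (66.9 and 73.0), and 4 in control only, the unfolded protein response factor XBP1 (15.4, score 1904), HSPB1 (11.1), HSF2 (8.97) and HSP90AB1 (6.79), at percentile 78.5. Of 41 nuclear-encoded genes of oxidative phosphorylation, 6 were in both, among them NDUFS3 (30.8 and 14.8), COX6A1 (15.7 and 24.4) and NDUFB8 (12.2 and 9.88), and 3 in control only, UQCRFS1 (10.7), NDUFS1 (8.97) and UQCRC1 (3.58), at percentile 94.8. With equal list lengths, the score floor, the upper 50% by fold enrichment, p or FDR 100 times smaller and 2 peaks or more per gene, in this order, control-only and DF2 siRNA-only genes numbered 1 and 2, 2 and 0, 1 and 1, 2 and 1, and 0 and 1 for oxidative phosphorylation, so the direction turned in 2 of the 5 settings. They numbered 4 and 0, 4 and 0, 4 and 0, 8 and 0, and 3 and 2 for DNA damage genes, and 2 and 0, 3 and 0, 1 and 1, 3 and 1, and 4 and 2 for heat shock genes. Equal list lengths dropped control peaks only, so control-only counts could only fall and DF2 siRNA-only counts could only rise. This also holds for the turn of oxidative phosphorylation in that setting.

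Cell cycle and autophagy genes were found more often in DF2 siRNA only than in control only. Of 35 cell cycle genes, 12 were in both lists, with E2F3 (159.6 and 83.0), the phosphatase CDC25A (62.8 and 79.0) and MKI67 (51.2 and 61.0) the strongest. The spindle kinase TTK (13.0) was in control only. E2F1 (16.5), CCND1 (15), CDK4 (13.2), CCNE1 (6.09) and PLK1 were in DF2 siRNA only. E2F1 and the CDK4 partner cyclin CCND1 are known for their part in entry into S phase. The difference of -4 stood at percentile 0.15 of the random lists, whose median was 1. Of 32 autophagy and lysosome genes, 16 were in both, with RPTOR of the mTOR complex (119.7 and 163) and the factors FOXO1 (108 and 81.8) and FOXO3 (79.3 and 49.7). LAMP1 (8.07) and ATG12 (8.02) were in control only, and TFE3 (19.2), ATG3 (13.8), ATG9A (13.2), ATG13 (9.82) and GABARAPL1 in DF2 siRNA only. The difference of -3 stood at percentile 0.72. Random lists had a median of 9 members with a peak for cell cycle and 10 for autophagy. The gene lists had 13 and 18 with a control peak alone. Lists with fewer such members leave less room for a difference, so both percentiles can be too extreme. The cell cycle genes numbered 1 in control only and 6 in DF2 siRNA only with equal list lengths, 1 and 3 with the score floor, 2 and 4 in the upper 50% by fold enrichment, and also with p or FDR 100 times smaller, and 2 and 2 with 2 peaks or more per gene. The autophagy genes numbered 0 and 7, 0 and 5, 1 and 1, 0 and 2, and 2 and 3 under these 5 settings, in the order given. Equal list lengths could only lower the control-only and raise the DF2 siRNA-only counts, since only control peaks were dropped. Of the members with a control peak, the number also in the DF2 siRNA list stood at percentile 61.4 for cell cycle and 74.6 for autophagy genes among random control genes matched on score. That match leaves out the genes in DF2 siRNA only.

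In the remaining lists, the difference stood at percentile 19.5 for the p53 pathway, 39.5 for NF-kB and interferon, 42.1 for glycolysis and lipids, and 95.2 for the markers of other cell types. Of 25 p53 pathway genes, 17 were in both lists, with MDM2 (158 and 46.5), MDM4 (136 and 40.2) and PPM1D (125 and 43.0). The death receptor gene FAS (28.8) was in control only and the CDK inhibitor gene CDKN1A (12.8, score 457, chromosome 6, 36682720 to 36684485) in DF2 siRNA only. Of 35 genes of the NF-kB and interferon response, 15 were in both, with IFIT2 (144 and 68.2), IFNAR1 (106 and 65.5) and ICAM1 (93.2 and 60.9), 3 in control only, among them IRF2 and SOCS1, and 2 in DF2 siRNA only (RELB, IRF3). Of 30 genes of glycolysis and lipid metabolism, 12 were in both, with the hexokinase HK2 (83.4 and 56.0), SQLE (59.6 and 48.7) and ACACA (55.9 and 65.7). Of the others, 2 were in control only, among them GPI (7.31), and PKM (18.3, score 1535) was in DF2 siRNA only. Of 22 markers of blood, epithelium, neurons and liver, none was in both. In control only were 3, among them PECAM1 (22.5) and SYP (5.10), and CD68 (6.92) was in DF2 siRNA only, with scores of 39, 6 and 10. A percentile describes these 2 lists only, and with 17 lists compared, some percentiles near 0 or 100 arise by chance.

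**Figure D3:**
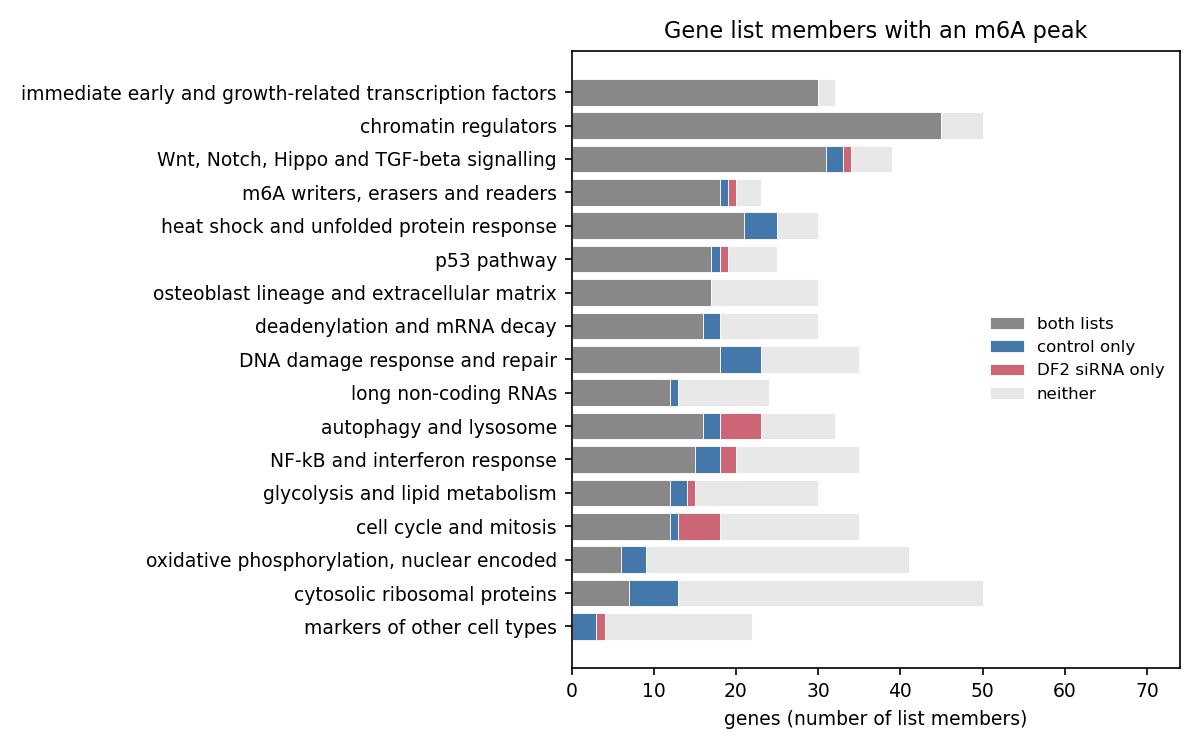
Members of each of the 17 gene lists (x axis, number of genes) with an m6A peak in both lists, in control only, in DF2 siRNA only or in neither. With all peaks kept, all 45 chromatin regulators and all 30 immediate early and growth-related factors with a peak had one in both lists, while 37 of 50 ribosomal proteins had none.

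The DF2 siRNA list came closest to the control list in number of peaks on the gene-rich chromosomes 19 and 16. Chromosome 19 had 1049 control peaks and 1012 DF2 siRNA peaks, a ratio of 0.965, and chromosome 16 had 880 and 826, a ratio of 0.939. Chromosome 18 had 269 and 195, a ratio of 0.725, chromosome 5 had 721 and 544, a ratio of 0.755, and chromosome 13 had 280 and 214, a ratio of 0.764. Across the 23 chromosomes, the log2 ratio correlated with the number of genes per Mb (Pearson r = 0.7255, Spearman rho = 0.789, 2 relations computed). Without chromosomes 17 and 19, which lay farthest from the median density, r was 0.765. Chromosomes are parts of the same 2 lists and not replicates, and this relation was sought after the data were seen.

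**Figure D4:**
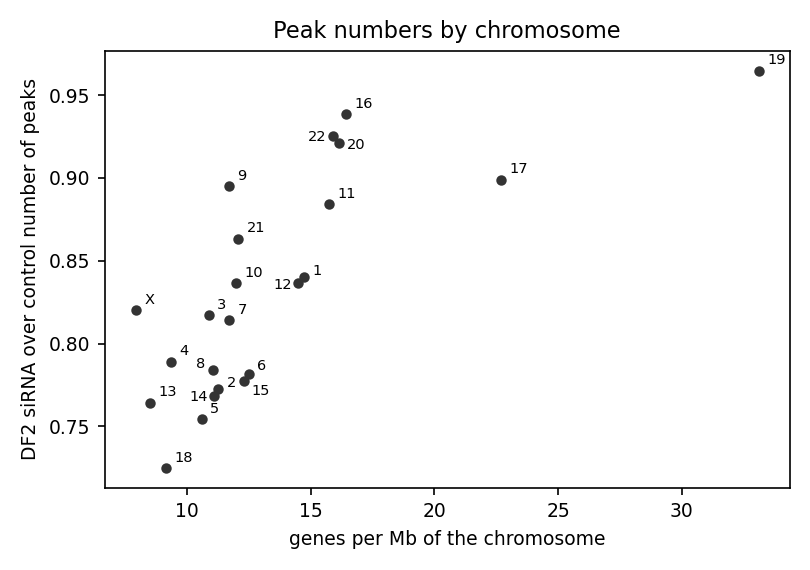
Number of DF2 siRNA peaks over number of control peaks (y axis, not starting at 0) against genes per Mb (x axis) for 23 chromosomes, 1 point each. The ratio goes from 0.725 on chromosome 18 to 0.965 on chromosome 19.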

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

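The alternatives that set a score floor or kept peaks of at most 400 nt or with 1 feature only were added after the data were seen. Of the values recomputed, 47 stayed within 1.5 times a count or within the interval of a share, 31 moved and 0 were counted as reversed. The cause was not tested. The stop codon, 3′ UTR and 5′ UTR differences, whose intervals held 0 with all peaks, changed sign in some settings without being counted as reversed. With the upper 50% by fold enrichment there were 7866 control and 6612 DF2 siRNA peaks, 85.3% of DF2 siRNA peaks overlapped, and 4606 genes were in both lists. With p or FDR 100 times smaller, 8292 DF2 siRNA peaks were left, and overlap was 67.9% of control and 88.4% of DF2 siRNA peaks. With equal list lengths, overlap was 81.4% and 83.7%, control-only genes numbered 1205, and the differences in share (DF2 siRNA minus control, percentage points) were -4.59 for stop codon peaks, 1.93 for 5′ UTR and -0.999 for non-coding RNA, against 0.930, 0.103 and -3.45 with all peaks. The stop codon difference thus changed sign, with an interval that held 0 for all peaks. Equal lengths dropped only control peaks of low fold enrichment, which raises the stop codon share of the control list. The change of sign in that setting cannot be told apart from this dropping. With the score floor, 80.0% of control peaks overlapped, 1260 genes were in control only, and the differences were -2.73, 1.17 and -1.42. In peaks of at most 400 nt they were 2.37, -0.936 and -4.43, with 4.46 for coding peaks, and in peaks with 1 feature only 5.63 for coding, 1.37 for 5′ UTR and -6.98 for non-coding RNA. The coding difference, 3.46 with all peaks, stayed positive and the non-coding one negative under every alternative run. A reciprocal overlap of 50% gave 61.5% and 73.3%, and overlap without strand 72.6% of control peaks. With 2 peaks per gene, 2529 genes were in both lists, and 154 members of the gene lists had control and 142 DF2 siRNA peaks. Among counts of single-list members of the gene lists, 78 stayed and 92 moved. No paired analysis was possible because each condition has 1 peak list. Not run were the motif alternatives, peak midpoints, a narrower stop codon window, and those for values per library (replicate block, leaving out a replicate, normalization, filter). Unknown depth limits every statement that a peak is missing from a list.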

Other observations

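The tests on zinc finger genes, the relation to gene density, the match of non-coding RNA peaks on score, the rank of YTHDF2 and the comparison of nuclear with cytoplasmic RNAs were chosen after the results were seen. Genes with a peak in control only were less often protein-coding. Of the RefSeq-matched genes, 94.0% of those in both lists (93.5 to 94.6%, 7180 genes), 84.1% of those in control only (82.1 to 85.9%, 1438 genes) and 94.4% of those in DF2 siRNA only (92.1 to 96.2%, 518 genes) were protein-coding. By Ensembl gene these groups held 7950, 2021 and 606 genes. The match thus left out the largest part among control-only genes, and the shares hold for matched genes only. Genes in DF2 siRNA only were shorter, with a median genomic span of 21.0 kb, against 30.4 kb for genes in both lists and 30.1 kb for genes in control only. At the shared peak of YTHDF2, the score in DF2 siRNA over that in control was 0.0438. Over 11780 overlapping pairs of peaks of the same gene the median of this ratio was 0.374, and 0.713% of the pairs had a lower ratio than YTHDF2. Of the 1977 pairs with a control score of 1000 or more, 26 had a lower ratio.

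Zinc finger genes of the ZNF, ZSCAN, ZKSCAN and ZFP families formed a large group with m6A, 399 genes. ZNF107 was among the strongest control-only genes, and the hypothesis was that such genes are lost more often than others in DF2 siRNA cells. The test went against it. Of 394 zinc finger genes in the control list, 92.6% were also in the DF2 siRNA list, above the 80.5 to 87.1% of random control genes matched on score. Without matching, the share was 82.9% for 8224 other genes. Zinc finger genes were thus not lost more often. Fold enrichment and number of peaks per gene were not matched, so the source of their higher share cannot be told from this. On chromosome 19 the share was 94.3% (89.5 to 97.4%) for 159 zinc finger genes and 87.9% (84.5 to 90.8%) for 447 other genes.

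The DF2 siRNA list had fewer peaks than the control list, with a ratio of 13219 to 15730. Fewer reads behind the DF2 siRNA list are a candidate explanation. With the score floor set in proportion to the scores, the ratio was 0.932, closer to 1 than with all peaks but below the 0.95 set in advance, so this explanation cannot be told apart from an effect of the knockdown while read numbers are unknown. The low scores of the control-only peaks go with either. By their headers, the control list gives a p-value and the DF2 siRNA list an FDR, so cuts on different quantities could also give lists of different lengths, which was not tested.

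The share of non-coding RNA peaks was lower in the DF2 siRNA list. With the score floor the difference was -1.42 percentage points (normal-approximation interval -2.12 to -0.732), so the interval did not hold 0. The floor only stands in for unknown read numbers, so this result cannot exclude fewer reads as the source. Control non-coding RNA peaks were overlapped in 52.7% of cases, and random control peaks matched on score in 49.0 to 52.1%, so they were not missed more often than other peaks of their score. Less RNA left over from the nucleus in DF2 siRNA cells was tested by the ratio of DF2 siRNA to control scores at shared peaks, which had a median of 0.237 (range 0.0486 to 1.08) over 6 nuclear RNAs such as MALAT1 and NEAT1 and of 0.418 (0.278 to 0.798) over 5 cytoplasmic non-coding RNAs such as NORAD, a quotient of 0.568. The ranges overlap and what a score counts is unknown. Shared peaks could also differ in width, as in MALAT1 with 1000 nt in control and 600 nt in DF2 siRNA. Fewer reads, less nuclear RNA, the low scores of these peaks and an effect of the knockdown therefore all stay open.

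Genes on gene-poor chromosomes were missing from the DF2 siRNA list more often than their scores would predict. Of 3603 control genes on chromosomes below the median density, 80.6% were also in the DF2 siRNA list. Random control genes matched on score gave 81.7 to 83.3%, so that the percentile was 0. What a score counts is unknown, so genes matched on it can still differ in how near their peaks lay to the cut. The result therefore cannot decide whether fewer reads were the only source. The loss of non-coding RNA peaks does not account for the relation of peak numbers to gene density, since r was 0.725 without them. The match of genes on score was not repeated without them. With non-coding RNA peaks kept, r was 0.697 with the score floor, 0.783 with equal list lengths and 0.574 in the upper 50% by fold enrichment. Base composition, which goes with gene density, could differ between the libraries, and neither this nor an effect of the knockdown was tested.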
